A study of Mus musculus with 6 samples.

How the data were processed

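RNA of 6 samples was measured on Affymetrix mouse arrays, 2 for each of E12.5 atrioventricular cushion, E17.5 atrioventricular valve and the MC3T3-E1 cell line. The deposited experiment description names the MOE430A array in one place and the 430 2.0 array elsewhere, and the table holds the 45101 probe sets of the 430 2.0 array. Per the labels' protocols, 2 amplification routes were used, and which samples had which is not stated.

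The deposited values are ratios on a linear scale. Per the deposited experiment description, the authors read the array images into GeneSpring GX 7.3, applied RMA with quantile normalization and referenced each gene to its median. In the table all 45101 probe sets have a median of 1 over the 4 valve arrays (tolerance 1e-05), so the MC3T3 ratios are relative to the valve. Whether the MC3T3 arrays were normalized together with the valve arrays is not stated. Ratios are held at a minimum of 0.01, reached by 102 and 110 probe sets of the MC3T3 arrays and by 1 of E17.5 replicate 1. Per the same description the authors kept 27195 probe sets with an intensity above 100, found 19455 that differed between the 3 sample types (p threshold 0.05 after Benjamini-Hochberg), listed 3119 at least 2-fold different between the stages, and took an MC3T3 value above 1.5 as expressed. A rerun of the authors' equal-variance test over the 3 groups on 45037 probe sets, without the intensity filter, gave 21000 past the threshold, of which 3169 were at least 2-fold different between the stages (2512 higher at E17.5 and 657 at E12.5). Without a test 3552 were.

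Control probe sets (64) were left out, as were 932 probe sets that name several genes and 9211 without a name. The remaining 34958 name 18193 genes, of which 18145 symbols matched the RefSeq table of the reference. A gene's value is the mean log2 ratio over its probe sets (9183 genes have 1, the most is 12), since the brightest probe set cannot be found on ratios. Fits used R 4.3.3 and limma 3.58.1 (lmFit and eBayes without a trend, on all 6 arrays with 3 residual and 4.57 prior degrees of freedom), with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p below 0.05 and at least 2-fold. A pattern holds genes called in the stated direction in both of its comparisons. Differences are given with the standard error of limma, and folds with a floor value are lower bounds.

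The groups, the tests and thresholds, the rule for naming genes and 24 gene lists (635 genes, 592 measured) were fixed before the data were examined. The lists cover valve mesenchyme transcription factors, cell cycle and DNA replication, collagens, elastic fibres, proteoglycans and hyaluronan, cartilage, tendon, osteoblast and bone mineral, matrix proteases, TGF-beta and BMP, Wnt, Notch, cardiomyocyte, endothelial, erythroid, macrophage and leukocyte, melanocyte and neural crest glia, smooth muscle and epicardial markers, immediate early genes, interferon response, cholesterol synthesis, glycolysis and sex-linked transcripts. Lists were tested with camera (preset correlation 0.01), adjusted over lists and comparisons together. By the naming rule the text gives, per comparison, the 6 largest called differences each way among genes whose arrays do not overlap between the groups, up to 2 called members each way of a list, the largest 8 of each pattern, and a fixed set of genes whether called or not. Lists of hepatocyte, lung epithelium and pan-cardiomyocyte sarcomere markers and of imprinted genes were added after the values were seen.

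The method was tested on simulated data with 18193 genes, of which 200 changed in each comparison. All genes changed 3-fold or 8-fold were called in the right direction and none of those changed 1.5-fold, with median estimates of 2.96 to 3.03, 7.97 to 8.13 and 1.48 to 1.52. Of the unchanged genes 2, 2 and 4 were called. Of 24 simulated lists 1 was shifted, by 0.5, and it alone was called. Genes were simulated as independent, so this does not test list calls where members are correlated. The correlation estimated in the measured lists reached 0.59, for macrophage and leukocyte markers.

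Alternatives were centring each array on its median, no fold threshold or 4-fold, an adjusted p of 0.01, eBayes with a trend and robust, a replicate block, each array left out, only the arrays compared, every probe set as its own item, probe sets ending in _x or _s left out, cameraPR and camera with an estimated correlation. Chosen after the values were seen were the most variable probe set of a gene, genes at the floor left out, only replicate 2 of both valve stages, and the authors' test. A filter on dim genes was not run since ratios hold no level, nor a pseudocount of 32 on the ratio scale, nor quantile normalization, which would force the MC3T3 distribution onto arrays centred on themselves.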

Results

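Gene expression was measured on Affymetrix Mouse Genome 430 2.0 arrays in 3 groups with 2 arrays each. Embryonic tissue of wild-type FVB/N mice gave 2 of the groups. These were the atrioventricular cushion at embryonic day 12.5 (E12.5), a swelling of mesenchyme under endocardium from which the valve leaflets form, and the atrioventricular valve at embryonic day 17.5 (E17.5), when the leaflets are elongating and laying down layered matrix. The remaining group was MC3T3-E1, an established mouse osteoblast progenitor line grown in culture. Each array carried pooled RNA, and the labels call the arrays of a group biological duplicates. How many embryos or cultures stand behind a pool is not given in the sources used here. The series title puts the question as which expression profiles remodelling valves share with osteoblast progenitors, and the design gives 3 comparisons between groups and the gene patterns common to pairs of them.

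The deposited values were ratios of each probe set to the median of its values on the 4 valve arrays, so that a log2 ratio of 0 is the middle of the valve arrays and the abundance of one transcript relative to another is not retained. The lowest ratio was 0.01 (log2 -6.64). In MC3T3 cells 90 genes reached this floor, and folds against it are given as lower bounds. Differences between groups are log2 differences with the standard error from limma, over 2 arrays per group and 18193 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of at least 2-fold. The number of arrays limits the precision: the median standard error was 0.091, and an exact permutation test of 2 arrays against 2 cannot give a p below 0.333. The p-values describe the spread between these pools.

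Replicate arrays lay close together, at a median absolute log2 difference over genes of 0.11 in E12.5 cushion, 0.0909 in E17.5 valve and 0.0792 in MC3T3. Arrays of the valve stages lay 0.281 to 0.315 apart. E12.5 cushion arrays lay 0.341 to 0.38 from MC3T3 arrays and E17.5 valve arrays 0.348 to 0.356, ranges that overlap. The percent of genes at least 2-fold apart was 6.04 to 7.77 between arrays of the valve stages. It was 20.2 to 22.6 between E12.5 cushion and MC3T3 arrays and 17.7 to 18 between E17.5 valve and MC3T3 arrays, ranges that do not overlap. Between group means the distances were 0.286 for the valve stages, 0.345 for E12.5 cushion and MC3T3, and 0.34 for E17.5 valve and MC3T3. Correlations of group means are not given, because values centred on the valve arrays fix much of them. The log2 ratio at the 3' end minus that at the 5' end of the Actb control transcript averaged -0.12 in E12.5 cushion, 0.13 in E17.5 valve and 0.18 in MC3T3. Each end is relative to its own median over the valve arrays. Such values can therefore be compared between groups but do not show how intact the RNA was. For Gapdh it was -0.03, 0.03 and -0.13. The 18S ribosomal RNA control stood at 1.63 in MC3T3 against -0.09 in E12.5 cushion, and the Pcx control at 0.72 against -0.08. The Tfrc control went the other way, with 0.22 in E12.5 cushion, -0.08 in E17.5 valve and -0.24 in MC3T3.

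From E12.5 to E17.5 the genes with the largest rises included 2 small proteoglycans, and those with the largest falls 3 embryonic globins. Aspn, which encodes the collagen-binding proteoglycan asporin, rose 43.7-fold (log2 difference 5.45 ± 0.15, adjusted p = 1.89e-06), and Ogn, encoding the related osteoglycin, rose 17.1-fold (4.09 ± 0.18, adjusted p = 9.27e-06). Rises also included the lipid transporter gene Abca8a (30.4-fold), the fibroblast growth factor carrier Fgfbp1 (23.6-fold), the airway secretoglobin Scgb3a2 (19.1-fold) and Igfbp6 (15.4-fold), which encodes a binder of insulin-like growth factors. The embryonic globin genes Hbb-bh1, Hba-x and Hbb-y, made by primitive red cells, fell, Hbb-bh1 at least 183-fold, Hba-x 95.7-fold and Hbb-y 13-fold. Amph fell 10.6-fold, Plek2 9.98-fold and the retinoic acid binding protein gene Crabp1 9.61-fold. In all, 850 genes rose and 335 fell, 6.51% of those tested, and 9740 passed the adjusted p without the 2-fold requirement, of which 3509 were higher and 6231 lower at E17.5, the reverse of the majority among called genes. The median log2 difference over all genes was -0.138, and with each array centred on its own median 1065 genes were higher and 211 lower at E17.5, 83.5% of calls higher against 71.7% as deposited.

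Some fibrous matrix genes rose. Of 35 measured genes for collagens and their assembly, 9 rose and none fell (camera adjusted p = 0.000151, and adjusted p = 0.223 with an estimated correlation). Col14a1, a collagen of tendon and other dense connective tissue, rose 5.63-fold (2.49 ± 0.10), Col6a3 3.86-fold (1.95 ± 0.09) and Col1a1, the main fibrillar collagen of valve and bone, 2.71-fold (1.44 ± 0.08). Of 16 tendon genes 7 rose and none fell (adjusted p = 0.000539, and adjusted p = 0.246 with an estimated correlation). Thbs2, a matricellular thrombospondin, rose 4.03-fold (2.01 ± 0.14) and Postn, encoding the collagen-crosslinking matricellular protein periostin, 2.65-fold (1.40 ± 0.10). Of 15 elastic fibre and microfibril genes 4 rose, Efemp1 (4.11-fold), Ltbp2 (3.38-fold), the tropoelastin gene Eln (2.03-fold, 1.02 ± 0.21) and Mfap5, the last chosen after its values were seen. This list did not pass its test (adjusted p = 0.29), its median was -0.04 and its mean 0.30, and the rise of Eln came to 0.65 without E17.5 replicate 1, below the 2-fold requirement. Counts of called members adjusted over the list alone were the same as over all genes for each of the 24 lists in each comparison.

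Cartilage and hyaluronan genes moved in both directions. Of 26 cartilage genes 4 rose and 6 fell (adjusted p = 0.449). Col2a1, the main collagen of cartilage, fell 7.01-fold (-2.81 ± 0.18) and Hapln1, the link protein that ties hyaluronan to proteoglycans, 6.07-fold (-2.60 ± 0.18), while Matn2 rose 3.55-fold and Cytl1 2.54-fold. Sox9, the transcription factor of chondrocytes and cushion mesenchyme, fell 2.1-fold (-1.07 ± 0.08), and came to -0.95 when arrays were centred. Of 28 proteoglycan and hyaluronan genes 3 rose, Aspn, Ogn and Dcn, and 2 fell, Hapln1 and the hyaluronan synthase gene Has2 (2.2-fold, in 1 of its 2 probe sets), with an adjusted p = 0.0812 for the list, which passed with cameraPR (0.0164) and without E12.5 replicate 2 (0.0231) and reached 0.233 without E12.5 replicate 1. The Has2 call was lost without E12.5 replicate 2 (-0.88), without E17.5 replicate 2 (-0.92) and with the most variable probe set (-0.94). Dcn was chosen after its values were seen. Versican (Vcan), a large proteoglycan of cushion matrix, differed by -0.30 ± 0.12 (adjusted p = 0.0675) and was not called. Of 30 osteoblast and bone mineral genes 1 rose, Postn, and 2 fell, the parathyroid hormone receptor gene Pth1r (3.58-fold) and Cthrc1 (2.24-fold), with an adjusted p = 0.521. The Cthrc1 call was lost without E17.5 replicate 2 (-0.97).

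Among early mesenchymal regulators some were lower at E17.5. Twist1, a transcription factor of mesenchymal progenitors, fell 8.18-fold (-3.03 ± 0.08, adjusted p = 1.89e-06) and Prrx2, a homeobox factor of embryonic mesenchyme, 4.45-fold (-2.15 ± 0.08). Msx2 fell 2.09-fold, and came to -0.95 when arrays were centred and -0.99 without E17.5 replicate 2. Tbx20, a T-box factor of the developing heart, differed by 0.19 ± 0.10 (adjusted p = 0.13). Of 37 valve mesenchyme transcription factors 10 fell and 2 rose, Meox2 (4.86-fold) and Zeb2 (2.18-fold). The list missed its threshold (adjusted p = 0.066), passed it when arrays were centred (adjusted p = 0.0168), with cameraPR and without E12.5 replicate 1 (0.0363) or E17.5 replicate 2 (0.0498), and ranged from 9.1e-05 to 0.117 over 9 other settings. It also had an adjusted p = 0.312 with an estimated correlation.

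Signalling lists changed in single members. Of 40 Wnt pathway genes 5 fell, among them Lef1 (4.14-fold) and Wnt4 (2.79-fold), and with them Fzd2, Rspo3 and Wnt2, chosen after their values were seen. The inhibitor gene Wif1 rose 3.79-fold, Dkk3 2.08-fold (a call lost without E12.5 replicate 1, 0.99, or E17.5 replicate 1, 0.95, and with only replicate 2 of both stages, 0.88) and, again chosen after its values were seen, Ccn4 rose. The list had an adjusted p = 0.0645 and an adjusted p = 0.371 with an estimated correlation, and passed in 6 of 9 other settings, which ranged from 0.0272 to 0.126. Of 41 TGF-beta and BMP genes Bmp10 rose 2.73-fold and the pathway inhibitors Smad6 and Bambi fell 2.3-fold and 2.22-fold (adjusted p = 0.362, with a median of -0.01). None of 20 Notch genes was called (adjusted p = 0.893). Of 38 matrix proteases and inhibitors Adamts12 rose 2.28-fold, and Adamts15 and Mmp11 fell 3.38-fold and 2.52-fold (adjusted p = 0.484). The proliferation marker Mki67 rose 2.6-fold (1.38 ± 0.09) and the centromere motor gene Cenpe 2.38-fold in 1 of its 2 probe sets, while the DNA replication genes Uhrf1 and Cdc6 fell 2.31-fold and 2.18-fold. Of 43 cell cycle and replication genes 3 rose and 4 fell (adjusted p = 0.141, passing when arrays were centred at 0.0388 and with cameraPR at 0.0316). The remaining called members, chosen after their values were seen, were Ccne2, which rose, and Gins2 and Mcm2, which fell.

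Markers of other cell types moved between the stages as well. Of 29 cardiomyocyte markers 7 rose and none fell (adjusted p = 1.81e-09, and adjusted p = 0.232 with an estimated correlation), led by the muscle creatine kinase gene Ckm (7.24-fold, 2.86 ± 0.08) and the calcium pump regulator gene Sln (6.22-fold, 2.64 ± 0.13). Of 27 endothelial and endocardial markers 3 rose, Npr3 (4.93-fold), Emcn (2.87-fold) and, chosen after its values were seen, Vwf, and Tal1 fell 2.35-fold, under 2-fold without E12.5 replicate 1 at -0.78 (adjusted p = 0.000576, and adjusted p = 0.324 with an estimated correlation). Of 13 epicardial and mesothelial markers 3 rose, Msln (8.81-fold), Muc16 (6.59-fold) and, chosen after its values were seen, Upk1b (adjusted p = 0.0456, and adjusted p = 0.599 with an estimated correlation). That call was lost when arrays were centred (adjusted p = 0.0684), with a replicate block (0.0504), and with E12.5 replicate 2 (0.133) or E17.5 replicate 2 (0.143) left out, in a range from 0.0128 to 0.143 over 9 settings. Erythroid markers fell in 7 of 14 (adjusted p = 0.0278, and adjusted p = 0.617 with an estimated correlation), a call lost without E12.5 replicate 1 (adjusted p = 0.0532) in a range of 1.11e-10 to 0.0532 over 9 settings. In that replicate 7 of the 14 erythroid markers stood at least 2-fold above E12.5 replicate 2. Of 25 macrophage and leukocyte markers 4 rose, Lyve1 (7.06-fold), F13a1 (2.71-fold) and, chosen after their values were seen, Mrc1 and Ptprc, and Pf4 fell 2.41-fold, under 2-fold without E12.5 replicate 1 at -0.73. The list had an adjusted p = 0.0255, and adjusted p = 0.727 with an estimated correlation, and came to 0.0539 when arrays were centred and to 0.672 without E12.5 replicate 2.

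Smaller groups completed the stage comparison. Of 14 melanocyte and neural crest glia markers 3 rose, Fabp7 (5.36-fold), Mlana (2.52-fold) and, chosen after its values were seen, the pigment cell regulator gene Mitf (adjusted p = 0.148). The smooth muscle genes Tagln and Cnn1 fell 2.36-fold and 2.28-fold among 15 (adjusted p = 0.249), with the Tagln call lost without E17.5 replicate 2 (-0.99). Of 26 interferon response and MHC class I genes 5 rose and none fell (adjusted p = 0.00696, and adjusted p = 0.573 with an estimated correlation), among them Gbp2 (7.04-fold), Rsad2 (5.23-fold) and, chosen after their values were seen, Bst2, Oasl2 and Ifit2. The glucose transporter gene Slc2a1 fell 2.67-fold among 15 glycolysis genes (adjusted p = 0.155), and none of 18 cholesterol synthesis genes was called (adjusted p = 0.379). Klf6, Ccn2 and, chosen after its values were seen, Klf4 rose among 23 immediate early genes (adjusted p = 0.986), though the Ccn2 call was lost without E12.5 replicate 1 (0.85) or E17.5 replicate 1 (0.85) and with only replicate 2 of both stages (0.66). Xist, expressed from the inactive X chromosome, rose 4.08-fold (2.03 ± 0.11), while the Y-linked genes Eif2s3y, Kdm5d and Uty were not called (0.82, 0.10 and 0.62). The 4 sex-linked transcripts passed as a list (camera adjusted p = 0.0277, and adjusted p = 0.324 with an estimated correlation). That call was lost when arrays were centred (adjusted p = 0.0522) and with some arrays left out. The sex of the pooled embryos is not given in the sources used here.

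**Figure D1:**
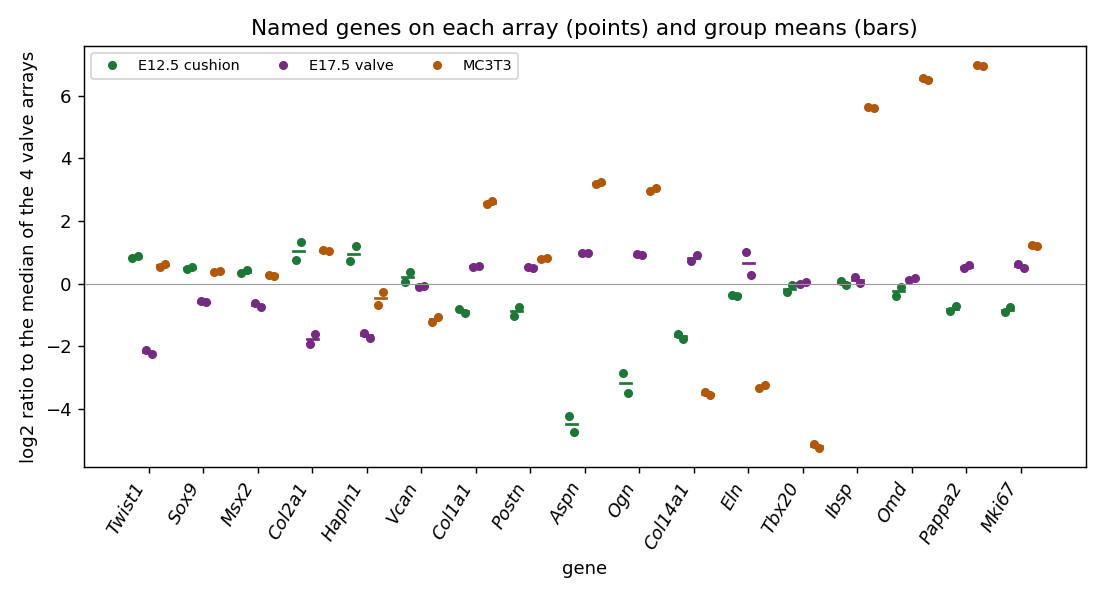
Log2 ratio to the median of the 4 valve arrays (vertical axis) for 17 genes, with a point for each array and a bar for each group mean of 2 arrays. Twist1, Sox9, Msx2 and Col2a1 lay at similar ratios in E12.5 cushion and MC3T3 and lower in E17.5 valve, and Ibsp, Omd and Pappa2 lay above 5 in MC3T3 and between -1 and 1 in both valve stages.

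Some transcripts of liver and blood differed between replicate arrays of a stage. Albumin (Alb), an abundant product of hepatocytes, stood at log2 ratios of 2.57 and 0.55 on the E17.5 arrays and -0.91 and -3.13 on the E12.5 arrays. Its difference between stages was 3.58 ± 0.78 (adjusted p = 0.00662), a call lost when eBayes was run with a trend and robustly (adjusted p = 0.0826, within 0.000369 to 0.0826 over all settings). Of 27 measured hepatocyte markers, a list chosen after the values were seen, 23 were at least 2-fold higher in E17.5 replicate 1 than in replicate 2, with a median difference of 2.01. Of all 18193 genes, 99 differed at least 2-fold between the E17.5 replicates, 64 between the E12.5 replicates and 3 between the MC3T3 replicates.

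**Figure D2:**
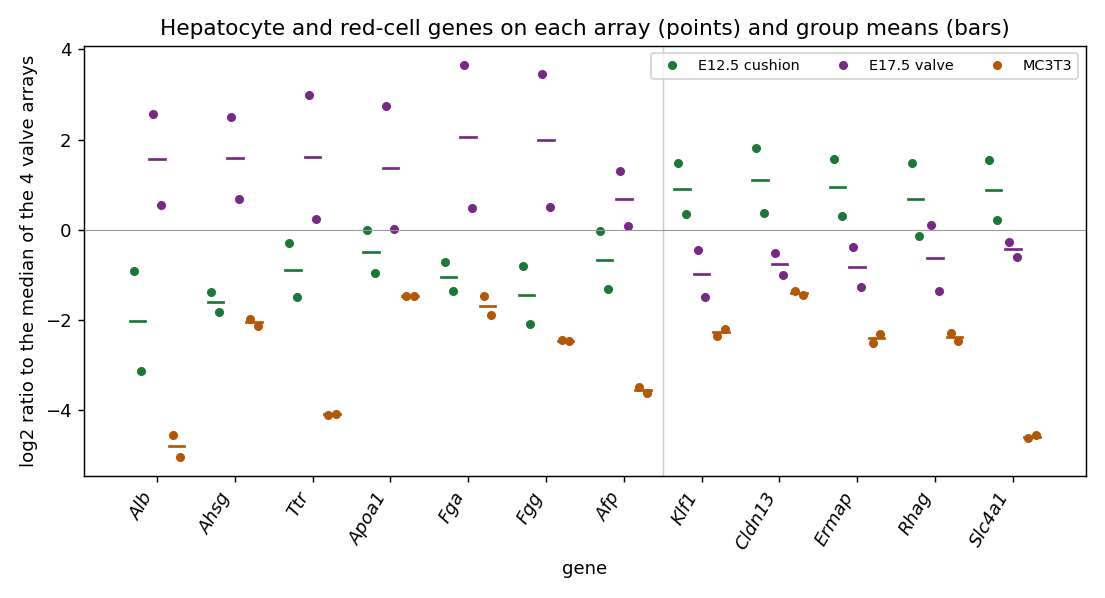
Log2 ratio to the median of the 4 valve arrays (vertical axis) for 7 hepatocyte genes and 5 red-cell genes, with a point for each array and a bar for each group mean. At E12.5 and at E17.5, replicate 1 lay above replicate 2 in each of the 7 hepatocyte genes and each of the 5 red-cell genes. The red-cell genes shown are a choice from 14 measured erythroid markers. Of those 14, 7 at E12.5 (median 1.00) and 2 at E17.5 (median 0.18) were at least 2-fold higher in replicate 1.

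Among the genes far higher in E12.5 cushion than in MC3T3 were 3 globins of primitive red cells. Hba-x, Hbb-bh1 and Hbb-y were at least 266-fold, 227-fold and 187-fold higher in the cushion, where MC3T3 stood at the floor. Rps4l, a ribosomal protein gene, was at least 139-fold higher and Cdkn1c, a maternally expressed imprinted inhibitor of the cell cycle, at least 104-fold, while the carbonic anhydrase gene Car2 was 111-fold higher. In the other direction MC3T3 cells had 219-fold more Pappa2 (log2 difference -7.78 ± 0.09, adjusted p = 2.43e-09), which encodes a protease of insulin-like growth factor binding proteins, and 205-fold more Aspn (-7.68 ± 0.15). Fgf7 was 113-fold higher in MC3T3, Omd, the bone proteoglycan osteomodulin, 110-fold, Efhd1 100-fold and the complement protease gene C1s1 97.7-fold. In all, 1862 genes were higher in E12.5 cushion and 1968 higher in MC3T3, 21.1% of those tested, and 5341 and 5141 without the 2-fold requirement, 760 and 483 at 4-fold, and 3600 and 5940 over probe sets.

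Among the genes far higher in E17.5 valve than in MC3T3 several stood at the floor in MC3T3 and have no order. Efemp1, encoding a fibulin of elastic tissue, was at least 175-fold higher in the valve (7.45 ± 0.13, adjusted p = 5.99e-09). The atrial and brain natriuretic peptide genes Nppa and Nppb were at least 152-fold and 138-fold higher, and the endothelial sialomucin gene Emcn at least 139-fold. Perp, a desmosome-associated membrane protein gene, was at least 148-fold higher and Mlf1 141-fold. Pappa2, Omd and Fgf7 were 86.6-fold, 83.6-fold and 81.6-fold higher in MC3T3, followed by Efhd1 (67.3-fold), Vit (54-fold) and the activin antagonist gene Fst (47.5-fold). In all, 1780 genes were higher in E17.5 valve and 1445 higher in MC3T3, 17.7% of those tested. Centring each array gave 1972 and 1156, but the majority turned over without the 2-fold requirement (3880 and 7062) and over probe sets (3522 and 3928), and the median log2 difference over all genes was -0.152.

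Many bone and fibrous matrix genes were higher in MC3T3 than in either valve stage. Of 30 osteoblast and bone mineral genes, 15 were higher in MC3T3 than in E12.5 cushion and 2 lower (adjusted p = 8.06e-06, and adjusted p = 0.223 with an estimated correlation). Against E17.5 valve 14 were higher in MC3T3 and 2 lower (adjusted p = 0.000151, and adjusted p = 0.226 with an estimated correlation). Ibsp, which encodes bone sialoprotein, was 48.5-fold and 45.4-fold higher in MC3T3 than in E12.5 cushion and E17.5 valve. Cthrc1 and Twist2 went the other way, with Cthrc1 8.99-fold and 4.01-fold higher in the valve stages. The Twist2 calls were lost without E12.5 replicate 1 against E12.5 cushion (0.94) and without MC3T3 replicate 2 against E17.5 valve (0.99). Of 35 collagen genes 20 were higher in MC3T3 than in each stage. Col8a1 was 43.2-fold and 41.4-fold higher there, and Col1a1 11.1-fold (-3.47 ± 0.08) and 4.11-fold (-2.04 ± 0.08). The basement membrane collagen gene Col18a1 was 8.1-fold higher in E12.5 cushion, and Col14a1 20.1-fold and Col4a1 5.8-fold higher in E17.5 valve. The collagen list had an adjusted p = 0.000377 against E12.5 cushion (adjusted p = 0.223 with an estimated correlation) and 0.0456 against E17.5 valve (adjusted p = 0.29 with an estimated correlation). The E17.5 call was lost without E12.5 replicate 2 (adjusted p = 0.0507, the highest of 9 settings that began at 0.00236).

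Of the proteoglycan, tendon and matrix protease lists, all 3 passed toward MC3T3 against E12.5 cushion, and against E17.5 valve the proteoglycan list passed and the others did in some settings. Of 28 proteoglycan and hyaluronan genes 13 were higher in MC3T3 than in E12.5 cushion and 3 lower, Gpc3, Hapln1 and Vcan (adjusted p = 0.000369, and adjusted p = 0.223 with an estimated correlation), and 15 were higher than in E17.5 valve and 2 lower, Gpc3 and Vcan (adjusted p = 0.0243, and adjusted p = 0.263 with an estimated correlation). Fibromodulin (Fmod) was 16.2-fold higher in MC3T3 than in E17.5 valve. Versican was 2.54-fold higher in E12.5 cushion and 2.06-fold in E17.5 valve than in MC3T3, each in 4 of its 8 probe sets, and fell to a difference of 0.97 against E17.5 valve without MC3T3 replicate 1. Glypican Gpc3 was 27.5-fold and 17.6-fold higher in the valve stages. Of 16 tendon genes 9 were higher in MC3T3 than in E12.5 cushion (adjusted p = 0.00183, and adjusted p = 0.263 with an estimated correlation) and 7 than in E17.5 valve (adjusted p = 0.16, and 0.029 with cameraPR), and Thbs4 and Col14a1 were lower in each. The tendon transcription factor gene Mkx was 31.3-fold and 28.1-fold higher in MC3T3. Among 38 matrix proteases and inhibitors 15 were higher in MC3T3 in each comparison, with Serpinf1 14.3-fold and 22.9-fold higher (adjusted p = 0.0278 against E12.5 cushion, adjusted p = 0.359 with an estimated correlation, and 0.0987 against E17.5 valve, 0.0301 there when arrays were centred and 0.00931 with cameraPR). Elastic fibre genes ran the other way, with 8 of 15 higher in E17.5 valve and none lower (adjusted p = 0.0124, and adjusted p = 0.392 with an estimated correlation). Eln was 15.4-fold and Efemp1 at least 175-fold higher. Against E12.5 cushion 7 were higher in the cushion and 2 lower, Mfap5 and Ltbp1 (adjusted p = 0.0987, and 0.00168 with cameraPR), of which the Ltbp1 call was lost without E12.5 replicate 1 (-0.97), and Mfap4 was 19.3-fold higher.

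Many heart regulators and markers of the cells that a valve dissection may hold were higher in the valve stages. Of 37 valve mesenchyme transcription factors 18 were higher in E12.5 cushion and 6 in MC3T3 (adjusted p = 0.003, and adjusted p = 0.226 with an estimated correlation), and 15 were higher in E17.5 valve and 8 in MC3T3 (adjusted p = 0.00662, and adjusted p = 0.232 with an estimated correlation). Tbx20 was at least 32.5-fold and 37.1-fold higher in the valve stages and Hey2 32.4-fold and 39.1-fold. The mesenchymal factors Prrx1 (11.3-fold and 8.17-fold) and Snai2 (4.61-fold against E12.5 cushion) were higher in MC3T3. Among 20 Notch genes 7 were higher in each stage (adjusted p = 0.0267 and 0.00662, and adjusted p = 0.272 and 0.246 with an estimated correlation), with Hey1 10.4-fold and 7.78-fold. Rbpj was higher in MC3T3 than in each stage, and Notch2 than in E17.5 valve, a call lost when arrays were centred (-0.98). Cardiomyocyte markers were higher in 27 of 29 at E12.5 (adjusted p = 2.59e-19, and adjusted p = 0.223 with an estimated correlation) and in 29 of 29 at E17.5 (adjusted p = 9.28e-28, and adjusted p = 0.223 with an estimated correlation). In MC3T3 19 of them had a probe set at the floor, and Actc1 and Tnni1 were at least 96.7-fold and 97.7-fold higher in E12.5 cushion. Endothelial markers were higher in 23 and 25 of 27 (adjusted p = 3.81e-12 and 6.14e-20, and adjusted p = 0.226 and 0.223 with an estimated correlation), with Tek at least 87.9-fold and 104-fold higher. Epicardial and mesothelial markers were higher in 12 of 13 at each stage (adjusted p = 3.93e-07 and 7.65e-11, and adjusted p = 0.312 and 0.263 with an estimated correlation), with Krt18 69.8-fold and 44.1-fold higher. Macrophage and leukocyte markers were higher in 18 and 19 of 25 (adjusted p = 2.35e-06 and 3.69e-11, and adjusted p = 0.44 and 0.324 with an estimated correlation), and erythroid markers in 11 and 8 of 14 (adjusted p = 0.000123 and 0.00089, and adjusted p = 0.392 and 0.446 with an estimated correlation).

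Metabolic lists separated the cultured cells from the tissue. Of 18 cholesterol synthesis genes 11 were higher in MC3T3 than in E12.5 cushion (adjusted p = 3.93e-07, and adjusted p = 0.324 with an estimated correlation) and 16 than in E17.5 valve (adjusted p = 5.47e-07, and adjusted p = 0.324 with an estimated correlation), and none was lower. Cyp51, a sterol demethylase gene, was 7.08-fold and 8.65-fold higher in MC3T3 and the squalene epoxidase gene Sqle 7.18-fold higher than in E17.5 valve. Glycolysis genes were higher in the tissue, 10 of 15 at E12.5 (adjusted p = 9.14e-07, and adjusted p = 0.343 with an estimated correlation) and 6 of 15 at E17.5 (adjusted p = 9.09e-08, and adjusted p = 0.324 with an estimated correlation), with Slc2a1 6.62-fold higher at E12.5. Of 26 interferon response and MHC class I genes 9 were higher in MC3T3 than in E12.5 cushion and none lower (adjusted p = 0.00363, and adjusted p = 0.542 with an estimated correlation), among them the antigen processing genes Tap2 (6.09-fold) and Psmb9 (4.38-fold). Against E17.5 valve 8 were higher in MC3T3 and 4 lower, Rsad2 (10.5-fold), Oasl2 (3.95-fold) and, chosen after their values were seen, Bst2 and Gbp2 (adjusted p = 0.251). Of 23 immediate early genes 5 were higher in MC3T3 than in E12.5 cushion and 3 lower (adjusted p = 0.0396, and adjusted p = 0.312 with an estimated correlation), and Myc was 6.99-fold higher. Klf4 was 6.11-fold higher in MC3T3, with Egr2, Ccn1 and Klf6, while Dusp1 (3.87-fold), Atf3 (2.27-fold) and Jun were higher in the cushion. Egr2, Ccn1, Klf6 and Jun were chosen after their values were seen. Against E17.5 valve 9 were higher in MC3T3 and 3 lower, Dusp1, Ccn2 and, chosen after its values were seen, Atf3 (adjusted p = 0.174, and 0.0314 with cameraPR). Cell cycle genes gave 5 of 43 higher in MC3T3 than in E12.5 cushion and 2 lower, Gins2 (0.89 without E12.5 replicate 1, under 2-fold) and Mcm7 (adjusted p = 0.674). The 5 were Mki67, Bub1 and, chosen after their values were seen, Cenpe, Hells and Kif11. There were 2 higher in MC3T3 than in E17.5 valve, Bub1 and Melk (adjusted p = 0.182). Mki67 was 4.12-fold higher in MC3T3 than in E12.5 cushion and differed by -0.66 ± 0.09 from E17.5 valve, under 2-fold.

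Signalling members split between tissue and cell line. In the TGF-beta and BMP list 10 of 41 genes were higher in E12.5 cushion and 9 in MC3T3 (adjusted p = 0.775), and 10 were higher in E17.5 valve and 6 in MC3T3 (adjusted p = 0.391). Bmp2 was 27.1-fold and 17.3-fold higher in the valve stages and the antagonist genes Chrdl1 and Fst were 31.2-fold and 30.6-fold higher in MC3T3 than in E12.5 cushion. Among 40 Wnt genes 12 were higher in E12.5 cushion and 8 in MC3T3 (adjusted p = 0.0456, and adjusted p = 0.359 with an estimated correlation), a call lost in 6 of 9 other settings, which ranged from 0.0307 to 0.168. Wnt2 was 23.2-fold and 10.5-fold higher in the valve stages and Ccn5 5.62-fold and 5.89-fold higher in MC3T3. Cartilage genes split too, with 4 of 26 higher in E12.5 cushion and 6 in MC3T3 (adjusted p = 0.716), and 3 higher in E17.5 valve and 7 in MC3T3 (adjusted p = 0.523). Col11a1, a fibrillar collagen of cartilage, was 31.8-fold and 29.1-fold higher in MC3T3, and Col9a1 (14.2-fold and 2.95-fold) and Cytl1 (6.14-fold and 15.6-fold) were higher in the valve stages. The others higher in a stage, chosen after their values were seen, were Hapln1 and Col9a3 at E12.5 and Epyc at E17.5. Of 15 smooth muscle markers 5 were higher in E12.5 cushion and 5 in MC3T3 (adjusted p = 0.809), and 5 in E17.5 valve and 4 in MC3T3 (adjusted p = 0.411). Cnn1 was 42.5-fold and 18.7-fold higher in the valve stages, with Myocd and, chosen after their values were seen, Synpo2, Des and Myl9. Actg2 was 14-fold and 8.72-fold higher in MC3T3, with Mylk and, chosen after their values were seen, Cald1 and Acta2 in each comparison and Lmod1 against E12.5 cushion. Of 14 melanocyte and neural crest glia markers S100b was higher in MC3T3 in each comparison. Higher in E12.5 cushion were 4 (adjusted p = 0.0649, and 0.0364 without E12.5 replicate 1), Erbb3 (4.81-fold), Fabp7 and, chosen after their values were seen, Kit and Mitf. Higher in E17.5 valve were 5 (adjusted p = 0.0183, and adjusted p = 0.263 with an estimated correlation, lost with cameraPR at 0.0508 in a range from 0.0104), Fabp7 (19-fold), Mitf and, chosen after their values were seen, Kit, Mlana and Erbb3.

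The Y-linked genes Eif2s3y and Uty were 7.53-fold and 3.35-fold higher in MC3T3 than in E12.5 cushion, and Xist at least 13.9-fold and 56.8-fold higher in the valve stages. With Kdm5d, chosen after its values were seen, 3 Y-linked genes were called higher in MC3T3 than in each stage. The list of 4 sex-linked transcripts was not called against E12.5 cushion (camera adjusted p = 0.364) or E17.5 valve (0.775).

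**Figure D3:**
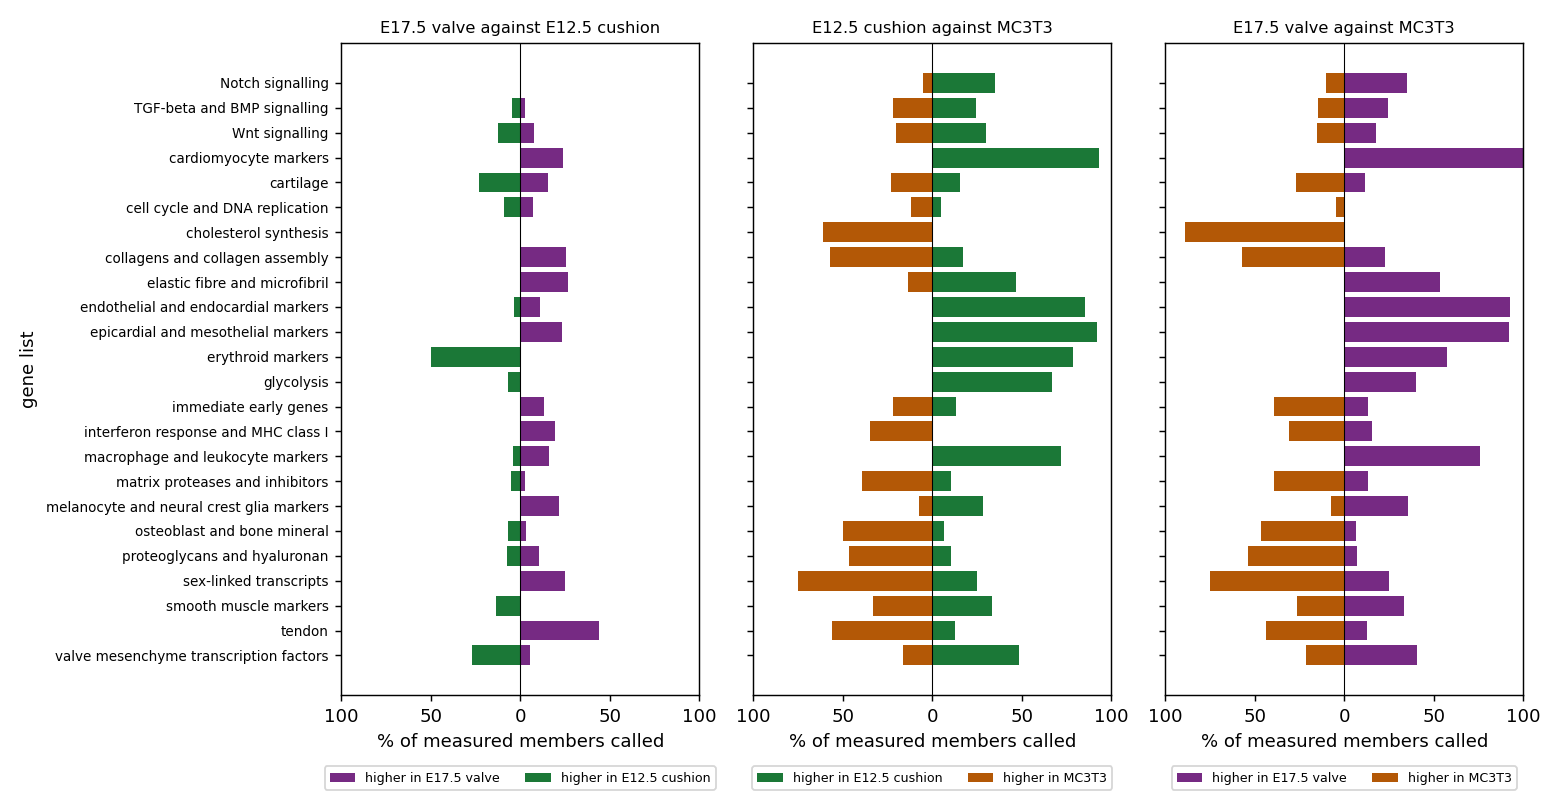
Percent of measured members of each of 24 gene lists that were called in the 3 comparisons (horizontal axis, called genes higher in the named group on either side of 0). Bars show the 29 of 29 cardiomyocyte markers higher in E17.5 valve than in MC3T3 on the right and the 16 of 18 cholesterol synthesis genes higher in MC3T3 on the left.

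Patterns over the 3 groups bear on the series' question of shared profiles. MC3T3 was the only cell line, so traits of osteoblast progenitors could not be told apart from those of cultured cells in general. Cell line and tissue also differed in culture and in the mixture of cells. MC3T3 and E12.5 cushion both exceeded E17.5 valve for 58 genes, led by Col2a1 and Twist1, and MC3T3 and E17.5 valve both exceeded E12.5 cushion for 390 genes, led by Aspn and Ogn. Both valve stages exceeded MC3T3 for 1351 genes and lay below it for 1053. E17.5 valve exceeded both other groups for 381 genes, and E12.5 cushion did for 201. Independent lists of the same lengths would overlap by 26.6, 91.9, 182, 156, 83.2 and 34.3 genes in that order. Simulated unchanged groups on the same design gave a mean of at most 0.1 gene and at most 2 genes in any of 100 simulations. No gene differed in these simulations, so they do not give the overlap to be expected where many genes differ. Each pair of comparisons shares the arrays of a group, and the 2 arrays were not divided between comparisons, so part of the excess may come from the shared arrays. A gene set apart in the shared group also enters both comparisons, so an excess over independent lists was to be expected and does not by itself show a shared profile. Of the 850 genes that rose from E12.5 to E17.5, MC3T3 was called above E12.5 cushion for 45.9% and below E17.5 valve for 44.8%. Of the 335 that fell, MC3T3 was called above E17.5 valve for 17.3% and below E12.5 cushion for 60%. The share called above the lower stage differed between the sets (Fisher's exact test, p = 3.59e-21, odds ratio 4.04, over genes, which are not independent). That test does not allow for the unlike numbers of genes higher in MC3T3, 1968 against E12.5 cushion and 1445 against E17.5 valve. Without the 2-fold requirement it was 2197 of 3509 risen and 3029 of 6231 fallen genes. At 4-fold it was 16 of 121 and 6 of 33, so the share was no longer higher among the genes that rose.

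The 58 genes higher in both E12.5 cushion and MC3T3 than in E17.5 valve included early mesenchyme and cartilage genes. Col2a1 differed by -0.01 ± 0.18 between E12.5 cushion and MC3T3 (adjusted p = 0.967) and by -2.82 ± 0.18 between E17.5 valve and MC3T3. Twist1 differed by 0.26 ± 0.08 between E12.5 cushion and MC3T3, under 2-fold, and stood 6.83-fold higher in MC3T3 than in E17.5 valve. The neuronal tubulin gene Tubb3, the stress kinase-like gene Trib3, Prrx2, the retinoic acid binding protein gene Crabp2, Kctd15 and Pth1r followed, with differences between valve stages of -2.43, -2.25, -2.15, -2.03, -1.94 and -1.84. E12.5 cushion minus MC3T3 was -0.63 for Tubb3, under 2-fold. For Trib3, Prrx2, Crabp2, Kctd15 and Pth1r it was -1.57, -1.40, -1.58, -1.15 and -1.14. These were thus also called higher in MC3T3 than in E12.5 cushion, and their levels were not alike. Sox9 and Msx2 fell between the stages but their differences between E17.5 valve and MC3T3 were -0.95 and -0.94, so that neither entered the pattern, though Msx2 came to -1.02 without E17.5 replicate 1, and with the most variable probe set Msx2 came to -1.50 and Sox9 to -1.18. Fisher's exact test over the 24 lists and 6 patterns, chosen after the deposited values were seen, gave adjusted p = 0.0153 for cartilage (Col2a1 and Hapln1), 0.0161 for proteoglycans and hyaluronan (Hapln1 and Has2) and 0.027 for valve mesenchyme transcription factors (Prrx2 and Twist1), each on 2 genes, of which the Has2 call was lost with some arrays left out. Here and for the patterns below this test takes genes as independent and does not allow for correlation between members. It also compares a list with all genes. A list with many members called in each single comparison can therefore pass without any further link between the comparisons. The pattern counted 34 genes when arrays were centred and 37 without E17.5 replicate 2.

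The 390 genes higher in both E17.5 valve and MC3T3 than in E12.5 cushion included matrix genes of tendon and fibrous tissue. Aspn stood 5.45 ± 0.15 higher in E17.5 valve than in E12.5 cushion and was higher again in MC3T3 (E17.5 valve minus MC3T3, -2.23 ± 0.15). For Ogn these differences were 4.09 ± 0.18 and -2.07 ± 0.18. Ccn3, a matricellular protein gene, and Cavin4, a muscle caveolar protein gene, differed by 3.84 and 3.37 between the stages. C1s1, the interferon-inducible Samd9l, the zinc finger gene Zfp51 and the alcohol dehydrogenase gene Adh1 followed at 2.56, 2.44, 2.35 and 2.52. E17.5 valve minus MC3T3 was -1.86 for Ccn3, -4.05 for C1s1 and -2.56 for Samd9l, so these stood higher again in MC3T3. For Cavin4, Zfp51 and Adh1 it was -0.96, -0.59 and 0.22, under 2-fold. By Fisher's exact test over genes taken as independent, the pattern held more collagen genes (6 of 35, adjusted p = 0.000758) and tendon genes (5 of 16, adjusted p = 0.000163) than unrelated lists would. Both lists also shifted in the single comparisons. Of the collagen genes 9 rose between the stages and 20 were higher in MC3T3 than in E12.5 cushion, and of the tendon genes 7 and 9. The test does not separate these shifts from a shared profile. Between the stages camera with an estimated correlation gave these lists adjusted p = 0.223 and 0.246. The members were as follows. The collagen list gave Col1a1, Lox, Col1a2 and the collagen VI genes Col6a1, Col6a2 and Col6a3, and the tendon list Postn, Thbs2, Dcn, Mfap5 and Tnc, of which Lox, Col1a2, Col6a1, Col6a2, Dcn, Mfap5 and Tnc were chosen after their values were seen. The 6 collagen genes, Thbs2 and Tnc were also called higher in MC3T3 than in E17.5 valve (Col1a1 4.11-fold). The pattern held 1 of 30 osteoblast and bone mineral genes, Postn. It also held 35 of 336 measured genes named Zfp with a number, a group chosen after the values were seen, where 7.2 would be expected (Fisher's exact test, p = 1.02e-14, with genes taken as independent).

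Some of the genes that set the cell line apart from both stages belonged to the lists described above. The 1351 genes higher in both stages than in MC3T3 held members of 11 lists that passed, among them 27 of 29 cardiomyocyte markers (adjusted p = 1.28e-26), 23 of 27 endothelial markers (adjusted p = 8.45e-21) and 17 of 25 macrophage and leukocyte markers (adjusted p = 1.27e-12). Bex1, Tnni1, Actc1, Myh7, Myl2, Cd24a, Csrp3 and Myl7 led it, each at the floor in MC3T3 and therefore in no order. The 1053 genes lower in both stages held members of 9 such lists, among them 20 of 35 collagen genes (adjusted p = 1.02e-14), 12 of 30 osteoblast genes (adjusted p = 7.82e-07) and 11 of 18 cholesterol synthesis genes (adjusted p = 1.04e-08), and were led by Pappa2, Omd, Fgf7, Efhd1, Vit, Ibsp, Col8a1 and the retinol dehydrogenase gene Adh7.

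Each valve stage also had genes above both other groups. E17.5 valve exceeded both for Fgfbp1 (log2 differences of 4.56 from E12.5 cushion and 4.45 from MC3T3), Abca8a, Scgb3a2, the prostaglandin D synthase gene Ptgds, the mitochondrial creatine kinase gene Ckmt2, Fgf12, the angiotensin receptor gene Agtr2 and Alb, of which Ckmt2, Agtr2 and Alb were also higher in E12.5 cushion than in MC3T3. This set of 381 held 7 cardiomyocyte markers (adjusted p = 2.01e-05) and members of 5 other lists that passed. These were 4 macrophage and leukocyte markers (Lyve1, F13a1, Mrc1 and Ptprc, adjusted p = 0.0101), 4 interferon response genes (Gbp2, Rsad2, Oasl2 and Bst2, 0.0113), 3 epicardial and mesothelial markers (Msln, Muc16 and Upk1b, 0.0123), 3 melanocyte and glia markers (Fabp7, Mlana and Mitf, 0.0147) and 3 elastic fibre genes (Efemp1, Ltbp2 and Eln, 0.0161), of which the Eln call between the stages was lost without E17.5 replicate 1 (0.65). Camera with an estimated correlation called none of these 5 lists between the stages, with adjusted p from 0.365 to 0.727. All 29 cardiomyocyte markers were called higher in E17.5 valve than in MC3T3. The 7 that rose between the stages therefore had to enter the set of 381. So were 19 of 25 macrophage and leukocyte markers and 12 of 13 epicardial and mesothelial markers higher there. For these 3 lists the set adds little to the comparison of the stages. E12.5 cushion exceeded both for Hbb-bh1, Hba-x, Hbb-y, Amph, Plek2, Crabp1, Pdzk1ip1 and Tcfl5, of which Hba-x, Hbb-y and Tcfl5 were also higher in E17.5 valve than in MC3T3. This set of 201 held 7 of 14 erythroid markers (adjusted p = 1.4e-09), 5 of 37 valve mesenchyme transcription factors (adjusted p = 0.000461), 4 of 40 Wnt genes (adjusted p = 0.00606) and 3 of 26 cartilage genes, Hapln1, Col9a1 and Col9a3 (adjusted p = 0.0147). Between the stages the erythroid list had an adjusted p = 0.617 by camera with an estimated correlation. In E12.5 replicate 1, 7 of its 14 members stood at least 2-fold above replicate 2. Mrc1, Ptprc, Bst2, Upk1b and Col9a3 were chosen after their values were seen, as were the factors and the Wnt genes. The factors were Gata5, Id1, Id2, Smad6 and Tbx2 and the Wnt genes Lef1, Rspo3, Wnt2 and Wnt4.

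**Figure D4:**
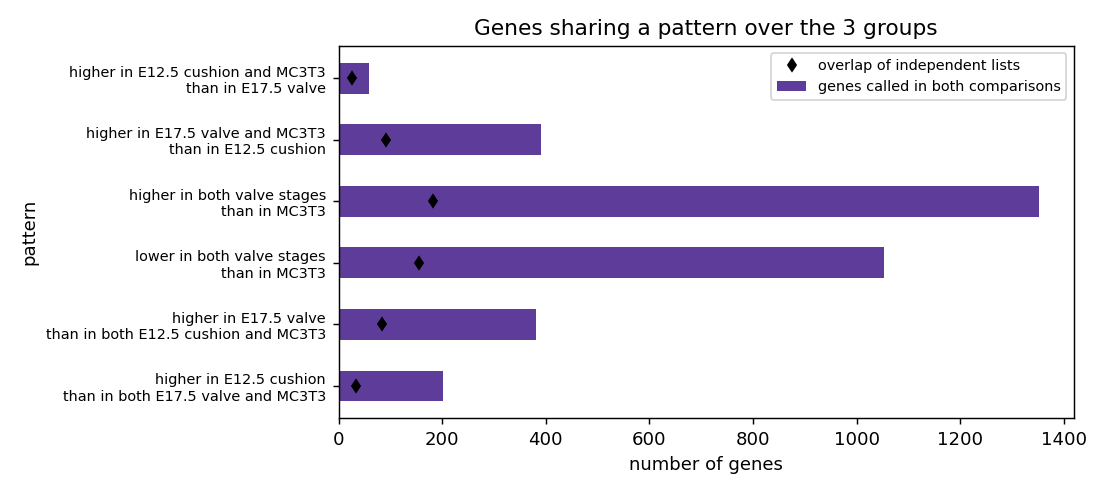
Number of genes (horizontal axis) called in both comparisons that make up each of 6 patterns over the 3 groups (bars) and the overlap of independent lists of the same lengths (diamonds). The counts run from 58 to 1351, each above its diamond, which lie between 26.6 and 182. The comparisons of a pattern share a group, so counts above the diamonds were to be expected.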

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

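The alternatives with the most variable probe set, without genes at the floor, with only replicate 2 of both valve stages and with the authors' test were chosen after the results were seen. Counts are given in the order E17.5 valve against E12.5 cushion, E12.5 cushion against MC3T3 and E17.5 valve against MC3T3, and for patterns in the order E12.5 and MC3T3 high, E17.5 and MC3T3 high, both stages high, both stages low, E17.5 above both and E12.5 above both. The fold threshold moved the counts most. Without it they were 9740, 10482 and 10942, with patterns of 3029, 2197, 3184, 4179, 1372 and 2849, so that genes common to E12.5 and MC3T3 then outnumbered those common to E17.5 and MC3T3. At 4-fold they were 154, 1243 and 1233, with patterns of 6, 16, 612, 288, 94 and 22. With every probe set as its own item they were 3503, 9540 and 7450, with patterns of 152, 1606, 2571, 3072, 894 and 402, and by the authors' test on probe sets 3169, 8900 and 7035, with patterns of 144, 1498, 2481, 2990, 822 and 350. The most variable probe set of each gene gave 2027 for the stages and, for patterns, 99 with E12.5 and MC3T3 high, 836 with E17.5 and MC3T3 high, 1630 with both stages low and 305 with E12.5 above both. These items differ in number or in averaging from the 18193 genes.

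Centring each array on its median gave 1276 genes between the stages (1065 higher and 211 lower at E17.5) and 34 with E12.5 and MC3T3 high. A threshold of 0.01 gave 1154, 3819 and 3187, and eBayes with a trend and robust 1146, 3811 and 3179. Leaving out probe sets ending in _x or _s gave 1174, 3765 and 3183, genes at the floor 1156, 3742 and 3137, and the arrays not compared 1173, 3835 and 3221. A replicate block gave 1202, 3835 and 3237 and patterns of 58, 391, 1356, 1053, 392 and 205. Whether replicate numbers pair the samples stayed open. Correlations of replicate deviations were 0.150 for E12.5 and E17.5, 0.058 for E12.5 and MC3T3 and 0.023 for E17.5 and MC3T3, and low values cannot exclude pairing. Only replicate 2 of both valve stages gave 1094, 3750 and 3242.

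With 1 array left out the counts ran from 1110 to 1318, 3746 to 3974 and 3193 to 3238. The patterns ran from 37 to 77, 357 to 430, 1308 to 1378, 1024 to 1097, 347 to 457 and 161 to 277. The 37 came without E17.5 replicate 2 and the 77 without E12.5 replicate 2. Distances between groups ran from 0.28 to 0.305, 0.342 to 0.366 and 0.34 to 0.352, and were 0.264, 0.319 and 0.327 over probe sets. The 3' minus 5' difference of the Actb and Gapdh controls ran from 0.13 to 0.19 for E17.5 minus E12.5 and from 0.05 to 0.15 for MC3T3 minus E12.5. The other controls gave 0.03 and 0.69.

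Of 72 list tests 40 were called with camera, 46 with cameraPR, 38 with the replicate block, 37 to 41 with 1 array left out and 0 with an estimated correlation, where the smallest adjusted p was 0.223 and 14 had an unadjusted p under 0.05. Of 720 list values under alternatives 642 kept the call or its absence, 58 lost it and 20 gained it. Of 5220 values of named genes 5114 kept it, 97 lost it, 9 gained it and none reversed. Between the stages Sox9 and Msx2 each came to -0.95 after centring, Eln to 0.65 without E17.5 replicate 1, and without E12.5 replicate 1 Pf4 to -0.73 and Tal1 to -0.78.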

Other observations

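The tests of explanations and the lists of hepatocyte, lung epithelium, imprinted and sarcomere genes were chosen after the results were seen. Of 28 measured imprinted genes, a list given no enrichment test, 14 were higher in E12.5 cushion and 14 in E17.5 valve than in MC3T3, and 3 (Impact, Kcnq1ot1 and Dcn, which is also in the proteoglycan list) and 1 (Impact) were lower. The growth factor gene Igf2 stood 6.52 and 6.61 (log2) higher in the stages, the growth inhibitor gene Cdkn1c 6.70 and 5.81, and Peg3 3.45 and 3.70. Impact differed by -1.49 and -1.54. Between the stages Dcn rose (1.60) and Nnat (-2.44) and Phlda2 (-1.26) fell. These genes were named after their values were seen.

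Of 19 lung epithelium markers 3 rose from E12.5 to E17.5, the secretoglobin genes Scgb3a2 (4.26) and Scgb3a1 (1.27) and Hopx. The surfactant genes Sftpb (-0.26) and Sftpc (0.93) and the club cell gene Scgb1a1 (0.55) were not called, and the list's median was -0.09.

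More genes were higher in both E17.5 valve and MC3T3 than in E12.5 cushion (390) than were higher in both E12.5 cushion and MC3T3 than in E17.5 valve (58), a ratio of 6.72 against 3.46 for independent lists of the same lengths, and so 1.95 relative to them (counting interval at the 0.05 level 1.48 to 2.56, with genes taken as independent and the arrays shared by comparisons not allowed for). Longer lists of genes higher at E17.5 stay open as the cause, since the relative ratio was 1.77 without a fold threshold (2197 and 3029 genes) but 0.53 at 4-fold (16 and 6 genes, interval 0.207 to 1.35). At 2-fold the lowest relative ratio with 1 array left out was 1.82 (without E12.5 replicate 1), which argued against a single array. The ratio of counts nevertheless ran from 4.96 without E17.5 replicate 1 to 11.6 without E17.5 replicate 2. Subtracting the trend with gene span gave a relative ratio of 2.09. That trend covered 0.26 to 0.50 (log2) over the comparisons, under the 2-fold requirement, so its subtraction could not decide whether span was the cause. The 4537 genes of shortest span held 32 shared by E17.5 and MC3T3 and 19 shared by E12.5 and MC3T3. The 4536 of longest span held 149 and 11, so gene span stays open as a cause. All genes had a median difference of -0.138 between the stages, an offset between array medians that takes genes from the larger count, while genes of long span were frequent among the 390 (279 above the median, 106 at or below it, Fisher's exact test, p = 1.35e-19). A maturing valve that takes on features of the cell line may account for the excess, and so may an amplification route that differed between groups, neither of which was tested, the latter because the samples' routes are not stated.

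Hepatocyte transcripts were higher in E17.5 replicate 1 than in replicate 2, by at least 2-fold in 85.2% of the 27 measured markers (23), with Fga 8.95-fold, Ttr 6.77-fold, Apoa1 6.68-fold, Alb 4.04-fold and Ahsg 3.53-fold. Of all genes 0.544% differed as much, which argued against a general difference between the arrays, and 98 of these 99 genes were higher in replicate 1. Liver RNA in that pool may be the source. As much higher were 2 of 14 erythroid markers (median 0.18), Klf1 (2.05-fold) and Rhag (2.76-fold), and 0 of 25 macrophage and leukocyte markers (median 0.04). Most blood cell markers thus did not rise with the hepatocyte markers. Liver RNA may itself hold red-cell transcripts, so the erythroid markers do not decide between liver and blood. S100a8 (4.68-fold), S100a9 (4.28-fold) and Adipoq (9.28-fold), chosen after their values were seen, leave some blood or fat open. The E12.5 arrays differed too, with 6 of the 27 markers at least 2-fold higher in replicate 1 and none in replicate 2 (median 0.58), among them Alb (4.67-fold), Fgg (2.46-fold) and Afp (2.43-fold). Unlike at E17.5, 7 of 14 erythroid markers (median 1.00) and 1 of 25 macrophage and leukocyte markers (median 0.52) were as much higher, so liver and blood could not be told apart there. From E12.5 to E17.5 the hepatocyte list had 11 members higher and 1 lower (Amn), with a median of 1.39. Beyond these marker lists no biological explanation was tested.

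Cardiomyocyte markers rose in 7 of 29 between the stages. All genes had a median difference of -0.138 between the stages, which lowers E17.5 values and argued against the offset between array medians. The 22 markers not called had a median of 0.26 (SD 0.34, 1.2-fold), and 13 pan-cardiomyocyte sarcomere genes, all within the cardiomyocyte list, a median of 0.14 with 1 called, Ttn. A larger share of heart muscle in the E17.5 pools and maturation of the muscle present could not be told apart, because ratios hold no level and abundant sarcomere transcripts may be saturated. The cardiomyocyte transcription factor gene Nkx2-5 was lower at E17.5 (-0.55 ± 0.10, adjusted p = 0.00233, under 2-fold), which goes against a larger share but is 1 gene whose own regulation is open.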
